A study of Mus musculus with 9 samples.

How the data were processed

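The series measured RNA in satellite cells, the muscle stem cells, isolated from hindlimb muscle of 9-week-old mice. Per the labels, 9 libraries fell into 3 groups of 3. The Control mice received oil, and the Mutant mice (Uhrf1-deficient in satellite cells) and the Cre Control mice received tamoxifen. Per the labels' protocols, Mutant mice were injected with tamoxifen intraperitoneally for 5 days as 150 µl of a 20 mg/ml solution. By the same protocols, Control and Mutant cells were seeded at 5000 cells/cm2 and cultured for 3 days. Per the labels' protocols, RNA of those 6 libraries was depleted of ribosomal RNA, prepared with a strand-specific kit and sequenced as paired reads. No protocol of the Cre Control libraries is given in the sources used here. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

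Per the submitters' processing notes, the Control and Mutant libraries list Trim Galore 0.6.6, STAR 2.7.6a, featureCounts 2.0.1 and DESeq2. The same notes list HISAT2 2.2.1 in place of STAR for the Cre Control libraries. The notes name the builds GRCm38 and mm10 for the first and GRCm38 for the second, with no role or order of the tools. How repeats were annotated and how reads mapping to several places were counted is not given in the sources used here.

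The authors deposited whole-number counts per repeat subfamily for the 6 Control and Mutant libraries, and per the file headers a comparison table of the same subfamilies with log2 fold changes, standard errors and p-values. For genes, the authors' deposited tables hold comparisons only, with no values per library. The first gene table gives mean TPM of all libraries, of Control and of Mutant, as deposited by the authors, with a log2 fold change, a standard error, a test statistic, a p-value and an adjusted p-value for 22631 genes. Its deposited log2 fold change equals the log2 ratio of the authors' mean TPM of Mutant plus 1 over that of Control plus 1, within 4.79e-08 for every gene. It therefore understates changes of genes with low TPM. The standard error in that table belongs to another estimate, the product of the deposited statistic and standard error, called the test estimate here. The ratio of TPM and the test estimate differed by more than 0.2 (log2) for 409 of the 8687 genes with a mean of at least 10 TPM, and had opposite signs for 20 of the 3877 genes with an adjusted p below 0.05. Levels and rankings use the TPM, and each value given with a standard error (SE) is the test estimate. How many libraries stand behind each mean of that table is not given in the sources used here. The overall mean of Uhrf1, 69.1 TPM, lay midway between its Control (118 TPM) and Mutant (20.4 TPM) means. Equal numbers of libraries per group would give that, and so would an average of the group means, so it does not settle the number.

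The second gene table, of 27775 genes, compares arms abbreviated PT and PUT. The labels do not say which groups these are, so the arms were given no group. Its deposited log2 fold changes divided by their standard errors equal the statistic. Per the file headers, the statistics of all comparison tables are score values of the authors' tests, and the mean levels of that table and of the repeat table are mean signals, that is, normalised counts averaged over libraries by the authors. Directions are stated relative to Uhrf1, which had a negative fold change in it. The planned comparisons of Mutant and of Control with Cre Control were not analysed here. The tables of the authors list 22518 and 27711 genes found in the GENCODE M21 annotation (GRCm38), from which positions and gene classes were taken.

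Repeat counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood with TMM factors over the repeats, after filterByExpr, on 3 Control against 3 Mutant libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per library are TMM-normalised CPM, from the repeat counts alone, so they are shares of repeat reads and not of all RNA. Total repeat counts lay between 1794698 and 2245124 per library. Wilson intervals (95%) of shares cover counting error only, since PCR reads without molecular identifiers are not independent molecules. On simulated repeat counts with 200 of the features changed, over 974 features tested, the same fit found 88% of 2-fold and 96% of 4-fold changes, and 2.65% of its calls were false. The simulated counts were independent draws, with no library deviating across many subfamilies as the library labelled Control 3 did. These shares therefore do not give the power of the fit on the real libraries. Libraries were compared in pairs with a chi-square test over subfamilies with at least 20 counts. Every pair differed by more than sampling noise, with a chi-square per degree of freedom of 3.19 for Control 1 and Control 2, the closest pair. Alternatives were DESeq2 1.42.0 on the same counts, other scalings and filters, the replicate number as a block, leaving out each library, stricter thresholds and the authors' deposited table.

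Gene results are the authors' adjusted p-values at a threshold of 0.05, with no test made here. For each of 15 gene lists and 6 marker lists of other cell types, fixed before the data were examined, members were counted over all genes and again with p-values adjusted over the list alone. The median fold change of a list with at least 5 members was placed among 10000 random lists of equal size matched on mean level in 20 bins, as a description of these tables. Here a percentile below 2.5 or above 97.5 is called outside the random range. Planted shifts of 0.5 (log2) in simulated lists of 20 genes over the 22631 genes of the first table were found in 100% of lists, and 5% of unshifted lists were outside. The simulated members were drawn independently. That share therefore does not show how often an unchanged list of genes regulated together would lie outside. Tests of lists that need values per library could not be run.

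The genes named were set by a rule fixed before the data were examined. Uhrf1, Cdkn1a, Pax7, Myod1, Myog, Myh3, Dnmt1 and Pcna were always named. Per table, the rule took the 10 highest and the 10 lowest fold changes among genes with an adjusted p below 0.05 and a mean level of at least 100, without predicted genes and pseudogenes. Per list, it took the 4 members changed most with a mean level of at least 10, and the 2 most abundant members of each marker list. For repeats it took the 8 highest and 5 lowest subfamilies with a mean of at least 100. That last rule was applied to the authors' deposited table, because the edgeR fit made no call. Genes and subfamilies outside the rule are said to be chosen after their values were seen. Trends with GC content and transcript length were removed by quadratic regression over protein-coding genes. Python 3.11.15 code used scipy and pandas.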

Results

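The data describe activated satellite cells, the stem cells of skeletal muscle, in culture. Uhrf1 is the factor that recruits the maintenance DNA methyltransferase to newly replicated DNA, and the series asks by its title how it bears on proliferation and differentiation of these cells. Gene expression was given as the authors' comparisons, and repeat expression as counts for 3 Control and 3 Mutant libraries with 1794698 to 2245124 repeat counts each. Depth per library is unknown for genes.

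The first comparison asked what differed between Uhrf1-deficient and Control cells. Control mice received oil and Mutant mice tamoxifen, so effects of the treatment cannot be told apart from those of Uhrf1 loss. This holds for genes and for repeats. The comparison with Cre Control, which also received tamoxifen, was not analysed here. Uhrf1 fell, from a mean of 118 TPM in Control to 20.4 TPM in Mutant in the authors' deposited table (test estimate −3.12, SE 0.60, adjusted p = 4.01e-06). Genes of DNA replication, mitosis and histone synthesis fell together, by modest amounts. Targets of p53, genes of antigen presentation and part of the interferon response rose. Of 22631 genes in the authors' deposited table, 3877 passed the threshold, 2044 of them higher and 1833 lower in Mutant. Uhrf1 (ENSMUSG00000001228) is a protein-coding gene on chromosome 17, from 56303321 to 56323486 on the plus strand (GRCm38). Its values in single libraries were not analysed here, so they could not check the labels. Whether the library labelled Control 3, whose repeat counts are described with the repeats, entered the Control means of the authors' deposited table is not given in the sources used here, and it could shift any of these means and fold changes.

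Cell cycle genes moved one way. In the authors' deposited table, 31 of the 36 genes of DNA replication and G1/S fell and 0 rose; adjusted over the list alone, 34 fell. The median log2 fold change of that list in the authors' deposited table was −0.43, percentile 0 of the random lists. E2f2, a transcription factor of S phase entry, fell from 43.4 to 22.5 TPM (test estimate −1.18, SE 0.10, adjusted p = 1.87e-27 in the authors' deposited table). The cyclins Ccne2 and Ccna2 fell with test estimates of −0.68 (SE 0.09) and −0.69 (SE 0.07) in the authors' deposited table, and Ccne1 with −0.68 (SE 0.10). Pcna, the sliding clamp of replication, fell from 400 to 292 TPM (test estimate −0.45, SE 0.06, adjusted p = 2.47e-11 in the authors' deposited table). Of the 32 genes of G2/M and mitosis, 25 fell and 0 rose in the authors' deposited table, and 29 fell adjusted over the list alone, with a median of −0.35 at percentile 0. Cdk1 (−0.61, SE 0.07), Ccnb1 (−0.53, SE 0.06), Ube2c (−0.53, SE 0.08) and Kif11 (−0.51, SE 0.06) were the members changed most, by the test estimates of the authors' deposited table. Of 67 replication-dependent histone genes, 41 fell and 0 rose in the authors' deposited table (46 fell adjusted over the list alone), with a median of −0.60 at percentile 0. Hist1h2bk fell with a test estimate of −0.76 (SE 0.07), Hist1h3c with −0.83 (SE 0.30), Hist1h2bn with −0.88 (SE 0.33) and Hist1h3a with −1.05 (SE 0.38) in the authors' deposited table. Histone genes are near-identical copies, so reads could be split among them. Hist1h1a and Hist1h4f were also among the 10 lowest abundant genes of the authors' deposited table, with test estimates of −0.73 (SE 0.07) and −0.75 (SE 0.08).

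Genes of the p53 response moved the other way. In the authors' deposited table, 19 of the 22 p53 targets rose and 0 fell; 20 rose adjusted over the list alone. Their median log2 fold change was 0.75, percentile 100 of the random lists drawn from the authors' deposited table. Trp53inp1, an inducer of apoptosis and autophagy, rose from 18.2 to 64.9 TPM (test estimate 1.94, SE 0.18, adjusted p = 3.11e-25 in the authors' deposited table). Ddit4l (1.89, SE 0.16), Pmaip1 (1.62, SE 0.12) and Btg2 (1.61, SE 0.27) followed in the authors' deposited table. Mdm2, the ubiquitin ligase of p53, rose from 154 to 346 TPM, and Ccng1, cyclin G1, from 158 to 384 TPM, in the authors' deposited table (test estimates 1.04, SE 0.14, and 1.27, SE 0.12). Of 8 CDK inhibitors, 1 rose and 1 fell in the authors' deposited table; adjusted over the list alone, 2 rose and 1 fell, and the list lay at percentile 62.5. The member that rose over all genes was Cdkn1a, which encodes p21 (474 to 726 TPM, test estimate 0.54, SE 0.13, adjusted p = 0.000597 in the authors' deposited table). Cdkn2c fell (−0.46, SE 0.10, adjusted p = 4.83e-05 in the authors' deposited table).

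Genes of muscle identity went both ways, and few of the differentiation genes passed the threshold. Pax7, which marks satellite cells, rose from 23.1 to 29.6 TPM (test estimate 0.35, SE 0.08, adjusted p = 0.000305 in the authors' deposited table). Of 19 satellite cell and quiescence genes, 5 rose and 4 fell in the authors' deposited table (5 and 5 adjusted over the list alone; percentile 37.7). Foxo3 (0.72, SE 0.07), Cxcr4 (0.55, SE 0.09) and Megf10 (0.45, SE 0.07) rose, while Fgfr4 fell (−0.35, SE 0.07), in the authors' deposited table. Myod1, a determination factor of the muscle lineage, fell slightly, from 1018 to 914 TPM (test estimate −0.17, SE 0.05, adjusted p = 0.00524 in the authors' deposited table). Of 41 genes of myogenic differentiation, 1 rose and 3 fell in the authors' deposited table; adjusted over the list alone, 1 rose and 2 fell. The median of these 41 was nevertheless −0.53, percentile 0, and 36 of them had a negative log2 fold change in the authors' deposited table. Their errors were wide, with a median SE of 0.50 in the authors' deposited table. Myogenin (Myog) was at 589 and 291 TPM in Control and Mutant in the authors' deposited table and did not pass the threshold (test estimate −1.03, SE 0.54, adjusted p = 0.219). Embryonic myosin heavy chain (Myh3) was at 172 and 78.6 TPM in the authors' deposited table (−1.14, SE 0.63, adjusted p = 0.257). Cardiac alpha actin (Actc1) fell from 141 to 28.5 TPM and Chrnd, a subunit of the acetylcholine receptor, from 64.6 to 51.7 TPM, while desmin (Des) rose from 763 to 892 TPM, in the authors' deposited table. Of 21 Notch pathway genes, 4 rose and 4 fell in the authors' deposited table, with the same counts adjusted over the list alone and a median at percentile 99.0 (95.2 by the mean). Notch3 (0.77, SE 0.06), Hes1 (0.46, SE 0.12) and Notch2 (0.38, SE 0.06) rose and Rbpj fell (−0.33, SE 0.05) in the authors' deposited table. Notch1, chosen after its values were seen, was counted as lower by its TPM (35.1 and 34.8) although its test estimate in the authors' deposited table was 0.45 (SE 0.08).

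Antigen presentation genes rose as a group and interferon response genes in part, in a table where macrophage and leukocyte markers also lay high (percentile 99.9 in the authors' deposited table). In the authors' deposited table, 12 of 17 antigen presentation genes rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.62 at percentile 100. Tap1, a subunit of the peptide transporter, rose from 10.9 to 27.6 TPM (test estimate 1.36, SE 0.12, adjusted p = 6.95e-26 in the authors' deposited table), and Tapbp (0.96, SE 0.14), H2-Q4 (1.03, SE 0.17) and Tap2 (0.79, SE 0.20) rose with it. Of 34 interferon response genes, 10 rose and 1 fell in the authors' deposited table (12 and 1 adjusted over the list alone), with a median of 0.27 at percentile 99.9 or above. Ifit2, named after its values were seen, was the member that fell (9.94 to 7.24 TPM in the authors' deposited table). Ifi27, from 23.4 to 60.2 TPM in the authors' deposited table (1.08, SE 0.15), was the only called member with a mean of at least 10 TPM. The other members that rose had lower means. Of 20 genes of the DNA methylation machinery, 9 fell and 0 rose in the authors' deposited table (10 fell adjusted over the list alone; percentile 0.71). Besides Uhrf1 these included Dnmt1, the maintenance methyltransferase (122 to 94.3 TPM, test estimate −0.37, SE 0.06, adjusted p = 3.2e-09), Tet3 (−0.71, SE 0.08), Cdca7 (−0.55, SE 0.11) and Hells (−0.43, SE 0.08) in the authors' deposited table. Germline genes, many of which are silenced by promoter methylation in somatic cells, stayed low. Of 37 in the authors' deposited table, 3 rose and 1 fell, with the same counts adjusted over the list alone and a median at percentile 99.9 (95.8 among members of at least 1 TPM). Hormad1, Tex15 and Xlr3a, named after their values were seen, rose, to 0.571, 0.755 and 2.59 TPM, in the authors' deposited table. The member that fell was Hsf2bp (−0.75, SE 0.24, adjusted p = 0.0147 in the authors' deposited table). Of 28 imprinted genes 6 rose and 3 fell in the authors' deposited table, also adjusted over the list alone (percentile 92.9, and 99.3 among members of at least 1 TPM). Impact (0.42, SE 0.08) and Sgce (0.42, SE 0.16) rose, and Peg10 (−0.35, SE 0.07) and Grb10 (−0.32, SE 0.05) fell, in the authors' deposited table. Of 50 clustered protocadherin genes 3 rose and 1 fell in the authors' deposited table (2 and 1 adjusted over the list alone; percentile 99.7, and 54.6 among members of at least 1 TPM). Pcdhgc3 fell (−0.16, SE 0.05), and Pcdhb2, Pcdhb17 and Pcdhgc5, named after their values were seen, rose, in the authors' deposited table.

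The most abundant changes lay partly outside these lists. Gpx3, a secreted glutathione peroxidase, rose from 55.0 to 253 TPM (test estimate 2.18, SE 0.20, adjusted p = 1.12e-25 in the authors' deposited table). Serpine2, a protease inhibitor, rose from 54.1 to 240 TPM in the authors' deposited table (2.11, SE 0.29). Sct, Ifitm3, Ak1, Gas6, Olfr1033 and Gsn completed the 10 highest with Ccng1 and Mdm2, with test estimates from 1.05 (Gsn, SE 0.07) to 1.58 (Sct, SE 0.26) in the authors' deposited table. Tspan9, a tetraspanin, was the lowest of the genes above the level set by the rule, at 144 and 62.3 TPM in the authors' deposited table (−1.09, SE 0.22). Cav1 (−0.56, SE 0.07) and Enah (−0.77, SE 0.17) also fell in the authors' deposited table. Of 27 extracellular matrix genes 10 rose and 2 fell in the authors' deposited table (11 and 2 adjusted over the list alone; percentile 99.9). Mmp2 (2.05, SE 0.38), Tnc (1.34, SE 0.34), Fn1 (1.32, SE 0.25) and Mmp14 (0.80, SE 0.18) rose most in the authors' deposited table.

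Markers of other cell types were low, with exceptions. Of 10 macrophage and leukocyte markers 2 rose and 0 fell in the authors' deposited table (percentile 99.9); Laptm5 rose from 25.1 to 84.8 TPM (1.75, SE 0.62), Cd68 from 3.46 to 6.27 TPM, and Fcer1g was at 3.22 and 19.3 TPM (2.48, SE 1.27, adjusted p = 0.203). Of 10 endothelial markers 1 rose (Tek) and 2 fell (Cdh5 and Pecam1) in the authors' deposited table (percentile 0.07), with Fabp4 at 9.14 and 9.66 TPM and Egfl7 at 6.10 and 5.41 TPM. Of 12 fibroblast markers 1 rose, which was Gsn, with 110 and 229 TPM in the authors' deposited table (percentile 19.7), and Thy1 was at 34.5 and 28.9 TPM. Of 9 smooth muscle and pericyte markers, 2 rose, Notch3 and Rgs5 (0.359 to 2.93 TPM), in the authors' deposited table (percentile 53.9; Cspg4 at 21.6 and 28.3 TPM). Of 8 Schwann cell markers 2 rose, Ncam1 (517 to 627 TPM), which muscle cells also express, and Mbp (1.75 to 3.94 TPM), in the authors' deposited table (percentile 56.4). Of 5 adipocyte markers 0 passed in the authors' deposited table (percentile 58.2; Pparg at 7.53 and 5.85 TPM). Cd68, Tek, Cdh5, Pecam1 and Rgs5 were named after their values were seen. For each of these 6 lists the counts adjusted over the list alone equalled those over all genes in the authors' deposited table.

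The second comparison asked which repeat transcripts differed between Mutant and Control, since DNA methylation silences retrotransposons. Intracisternal A particles (IAP), a family of endogenous retroviruses, were high in all 3 Mutant libraries, low in Control 1 and Control 2, and high in the library labelled Control 3. The internal sequence IAPEz-int stood at 4374 and 5879 CPM in Control 1 and Control 2, at 140924 CPM in the library labelled Control 3, and at 93193, 119442 and 185414 CPM in the Mutant libraries. Its group means were 50392 ± 78407 CPM (SD, n = 3) in Control and 132683 ± 47515 CPM (SD, n = 3) in Mutant. With all 6 libraries, 0 of 984 subfamilies passed in edgeR's quasi-likelihood test, 111 had an unadjusted p below 0.05, and DESeq2 called 17, 14 of them higher and 3 lower in Mutant. Without the library labelled Control 3, an alternative that decides the count, edgeR called 73 subfamilies, 69 higher and 4 lower, among them 15 of the 23 IAP subfamilies. These same counts single out that library, so all values given without it hold only under its exclusion.

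IAPEz-int made up 0.501% of repeat counts in Control 1 (95% Wilson interval 0.491 to 0.511) and 0.675% in Control 2 (0.664 to 0.686). Its share was 13.1% in the library labelled Control 3 (13.1 to 13.2), and 9.29%, 11.1% and 16.3% in the Mutant libraries. Over all 6 libraries its log2 fold change was 1.40 (SE 1.19; edgeR adjusted p = 0.638), and without the library labelled Control 3 it was 4.69 (SE 0.28; edgeR adjusted p = 2.32e-06). IAPLTR1_Mm, a long terminal repeat of the family, followed with 1.37 (SE 1.15) and 4.51 (SE 0.27), IAPA_MM-int with 1.42 (SE 1.25) and 5.42 (SE 0.31), and IAPLTR1a_Mm with 1.16 (SE 0.88) and 3.25 (SE 0.24). MMERVK10D3_I-int, of a related family, had 0.76 (SE 0.54) and 1.81 (SE 0.19). Of 23 IAP subfamilies edgeR called 0 over the 6 libraries, also adjusted over the list alone, and DESeq2 called 0. Of 256 subfamilies listed by name as other ERVK, edgeR called 0, or 2 adjusted over the list alone, and DESeq2 called 8, all higher. Their sums were 54773 ± 5147 CPM in Control and 61939.6 ± 2808 CPM in Mutant (SD, n = 3 each). That list takes every name starting with RLTR. Names starting with RLTR4 or RLTR6 are therefore counted again with the MuLV and other ERV1 elements. Among them, RLTR6_Mm alone averaged 2032 CPM in Control and 5477 CPM in Mutant, so the sums do not describe ERVK elements only.

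The subfamilies named here of VL30, a family of retroviral elements, were higher in each Mutant library than in each Control library. They are listed by name with MuLV and other ERV1 elements, which summed to 37930.3 ± 14404 CPM in Control and 70711 ± 10978 CPM in Mutant (SD, n = 3 each). Of the 43 subfamilies of that list edgeR called 0, or 1 adjusted over the list alone, and DESeq2 2, all higher. The list takes every name starting with RLTR4 or RLTR6, such as RLTR44-int, so its sums may not describe ERV1 elements only. MMVL30-int averaged 23049 ± 9934 CPM (SD, n = 3) in Control and 49715 ± 8019 CPM (SD, n = 3) in Mutant, a ratio of 2.16, with 34422 CPM in the library labelled Control 3. Its log2 fold change was 1.11 (SE 0.27), which did not pass over all subfamilies (edgeR adjusted p = 0.217). Its long terminal repeats RLTR6_Mm and RLTR6C_Mm had 1.43 (SE 0.37; edgeR adjusted p = 0.218) and 1.38 (SE 0.32; edgeR adjusted p = 0.187), and DESeq2 called the last of these (adjusted p = 0.0492). RLTR1B-int, chosen after its values were seen, is counted by its name with the other ERVK elements. It averaged 122 ± 38.2 CPM in Control and 270.2 ± 16 CPM in Mutant (SD, n = 3 each). Its log2 fold change of 1.16 (SE 0.19) passed in DESeq2 (adjusted p = 3.6e-11) and not in edgeR (adjusted p = 0.134). Without the library labelled Control 3, edgeR called all 4 of these subfamilies, with 1.52 (SE 0.11; adjusted p = 9.04e-06) for MMVL30-int, 1.99 (SE 0.17) for RLTR6_Mm, 1.88 (SE 0.13) for RLTR6C_Mm and 1.43 (SE 0.10) for RLTR1B-int.

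Other classes differed little. LINE-1 elements together made up 103345 ± 2056 CPM in Control and 101310 ± 1627 CPM in Mutant (SD, n = 3 each), and SINE elements 426572 ± 2735 and 417847 ± 426 CPM. MERVL and its MT2 repeats, which are active in early embryos, stood at 11481 ± 172 and 11633 ± 119 CPM (SD, n = 3 each). Satellite repeats stood at 8526 ± 634 and 9514 ± 924 CPM (SD, n = 3 each). Over the 6 libraries, edgeR called 0 members of these 4 classes, where DESeq2 called 1 LINE-1 subfamily higher and 2 lower; adjusted over the list alone, edgeR called 1 MERVL or MT2 subfamily higher and 0 of the others. L1_Mm, MER102c and L1ME3Cz were the lowest subfamilies by the rule, with log2 fold changes of −0.40 (SE 0.12), −0.45 (SE 0.09) and −0.33 (SE 0.06), called by DESeq2 and not by edgeR over the 6 libraries. Without the library labelled Control 3, edgeR called them too (−0.48, SE 0.11; −0.52, SE 0.09; −0.37, SE 0.07), and in the 4 classes it called 2 LINE-1 subfamilies higher and 2 lower, 1 MERVL or MT2 and 1 SINE subfamily higher, and 0 satellites. With 3 libraries against 3, a 2-sided exact permutation test of a single subfamily cannot give a p below 0.1.

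In the authors' deposited table of repeats, 63 subfamilies passed, 60 higher and 3 lower. A DESeq2 fit of the counts without the library labelled Control 3 gave the fold changes of the authors' deposited table within 0.00134 (log2) for all 1093 subfamilies in both, while a fit of all 6 libraries differed by up to 4.25. IAPEz-int had a log2 fold change of 4.69 (SE 0.42) and MMVL30-int of 1.51 (SE 0.19) in the authors' deposited table. By class, the calls of the authors' deposited table were 15 IAP, 20 other ERVK, 7 MuLV and other ERV1, 1 SINE and 1 satellite subfamilies higher, and 2 LINE-1 subfamilies higher and 2 lower, with the rest outside the classes listed here. Subfamilies with names starting with RLTR4 or RLTR6 are counted both as other ERVK and as ERV1 elements.

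**Figure D1:**
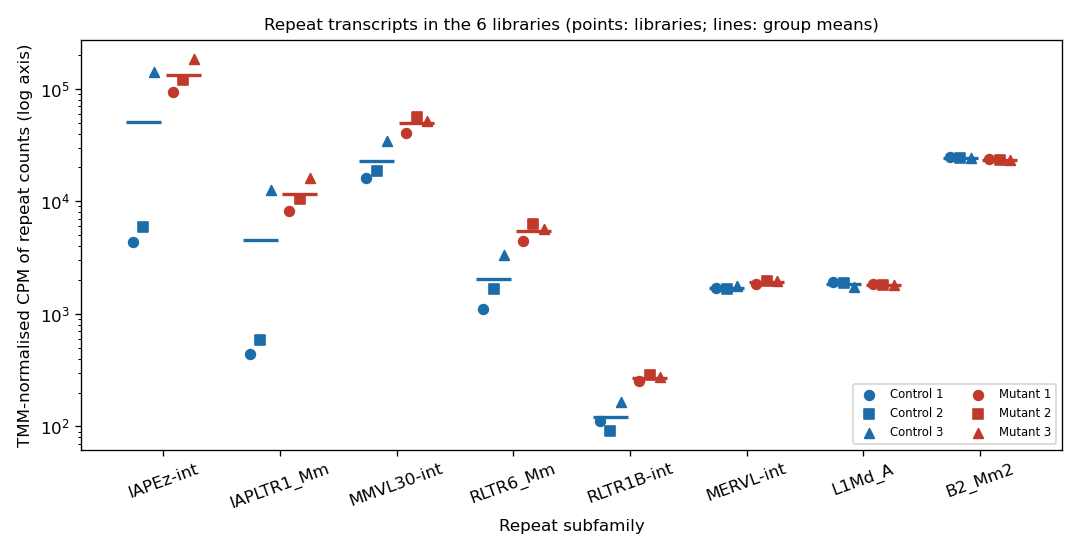
TMM-normalised CPM of repeat counts (log axis) of 8 repeat subfamilies in 3 Control (blue) and 3 Mutant (red) libraries; points are libraries and lines are group means. For IAPEz-int the library labelled Control 3 (140924 CPM) lies among the Mutant libraries (93193 to 185414 CPM), while L1Md_A and B2_Mm2, chosen after their values were seen, differ little.

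The third comparison is the authors' second gene table, of the arms PT and PUT. Uhrf1 had a log2 fold change of −4.0 (SE 0.27, adjusted p = 1.81e-48) in the authors' deposited table, where its level differed by a factor of 16. Replication and histone genes were again lower on the side with less Uhrf1, and germline genes were higher there. Mitochondrial RNAs were among the abundant genes with the highest fold changes. Of 27775 genes, 13112 passed in the authors' deposited table, 6984 with positive and 6128 with negative fold changes, so that 47.2% of all genes differed. Whether the arms were prepared and aligned alike is not known from the labels. Across 9514 protein-coding genes with a mean level of at least 100 in the authors' deposited table, fold changes went with GC content (Spearman rho −0.45, over genes, which are not independent replicates).

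In this authors' deposited table, 27 of 36 replication genes had negative and 2 positive fold changes that passed (28 and 2 adjusted over the list alone), with a median of −0.79 at percentile 0. Chaf1a, a chaperone that deposits histones at replication forks, had −1.50 (SE 0.08), Lig1 −1.44 (SE 0.09), Pold1 −1.39 (SE 0.10), and the exception Ccne2 1.40 (SE 0.12) in the authors' deposited table; Pcna had −0.43 (SE 0.08). Relative to other protein-coding genes, and over members with a mean level of at least 100, the median of that list in the authors' deposited table was −0.70 before and −0.64 after removal of the trend with GC content and length. Of 66 histone genes, 53 had negative and 1 positive fold changes in the authors' deposited table, also adjusted over the list alone (percentile 0). H4c14 had −2.17 (SE 0.10), H1f1 −2.13 (SE 0.16), H1f5 −1.98 (SE 0.07) and H2bc21 1.93 (SE 0.34) in the authors' deposited table. The histone median, over the 62 members at that level, went from −0.62 to −0.14 with removal of that trend from the authors' deposited table. Mitotic genes went both ways, 18 of 32 negative and 7 positive in the authors' deposited table (18 and 8 adjusted over the list alone; percentile 34.7). Bub1b (−1.16, SE 0.08), Cdc20 (−1.14, SE 0.07) and Birc5 (−1.09, SE 0.09) were opposite to Cdk1 (0.92, SE 0.09) in the authors' deposited table. With removal of the same trend from the authors' deposited table, the median of mitotic genes went from −0.15 to −0.38, and that of the 13 antigen presentation genes at that level from −0.15 to 0.14. Other medians also moved, from 0.28 to 0.19 for p53 targets and from 0.26 to 0.04 for imprinted genes. Those of CDK inhibitors (−0.26 to 0.26) and interferon response genes (−0.15 to 0.19), with 5 members each at that level, changed sign.

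Of 22 p53 targets, 11 were positive and 3 negative in the authors' deposited table, also adjusted over the list alone (percentile 98.4, and 96.9 by the mean). Perp (1.98, SE 0.54), Trp53inp1 (1.56, SE 0.10), Fas (1.32, SE 0.40) and Pmaip1 (1.21, SE 0.14) led the list in the authors' deposited table, and Cdkn1a had 0.27 (SE 0.08, adjusted p = 0.00223). Among 8 CDK inhibitors 3 were positive and 2 negative in the authors' deposited table, also adjusted over the list alone (percentile 78.7), from Cdkn2c (−1.0, SE 0.10) and Cdkn2d (−0.43, SE 0.15) to Cdkn1b (0.54, SE 0.13) and Cdkn2b (0.90, SE 0.27). Of 23 germline genes 13 were positive and 0 negative in the authors' deposited table, also adjusted over the list alone, with a median of 1.99 at percentile 99.9 or above, and at percentile 93.5 among members with a mean level of at least 10. Tex15 (2.74, SE 0.58), Sycp3, a protein of the meiotic chromosome axis (2.36, SE 0.49), Xlr3a (1.99, SE 0.37) and Brdt (1.94, SE 0.64) had mean levels of 10.9 to 40.9 normalised counts in the authors' deposited table. DNA methylation genes were 11 negative and 3 positive of 19 in the authors' deposited table, also adjusted over the list alone (percentile 3.13), with Dnmt1 at −0.78 (SE 0.07), Dnmt3a at −0.93 (SE 0.11), Dnmt3b at −1.20 (SE 0.30) and Cdca7 at −0.89 (SE 0.12).

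Muscle genes showed no common direction in this authors' deposited table. Of 41 genes of myogenic differentiation 6 were positive and 6 negative, also adjusted over the list alone (percentile 82.1), in the authors' deposited table. Myog had −0.34 (SE 0.52, adjusted p = 0.635), Myh3 −0.12 (SE 0.64, adjusted p = 0.901) and Myod1 −0.15 (SE 0.06, adjusted p = 0.0229) in the authors' deposited table. Mef2c (2.32, SE 0.67) and Klhl41 (1.80, SE 0.48) lay opposite to Tnnc1 (−1.89, SE 0.49) and Tnni2 (−1.70, SE 0.30) in the authors' deposited table. Pax7 had −0.43 (SE 0.10, adjusted p = 0.000128) in the authors' deposited table, opposite in sign to its value in the first table. Of 19 satellite cell genes 6 were positive and 8 negative in the authors' deposited table (6 and 9 adjusted over the list alone; percentile 25.1), with Col5a3 at −1.30 (SE 0.15), Itga7 at −1.09 (SE 0.07), Fgfr4 at −1.0 (SE 0.08) and Pax3 at 1.01 (SE 0.31). Of 20 Notch genes 4 were positive and 6 negative in the authors' deposited table, also adjusted over the list alone (percentile 72.4), including Maml2 (1.18, SE 0.20) and Lfng (−1.04, SE 0.15).

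Immune genes did not move together there. Of 17 antigen presentation genes 2 were positive and 5 negative in the authors' deposited table, also adjusted over the list alone (percentile 15.7), with B2m at 2.29 (SE 0.12) and Psmb10 at −1.78 (SE 0.18). Of 27 interferon genes 5 were positive and 3 negative in the authors' deposited table, also adjusted over the list alone (percentile 21.2), among them Parp14 (1.09, SE 0.36), Ddx58 (1.05, SE 0.29) and Ifi35 (−1.19, SE 0.20). Of 33 imprinted genes 11 were positive and 7 negative in the authors' deposited table, also adjusted over the list alone (percentile 87.1), with H19 at −1.38 (SE 0.08) and Mest at 1.46 (SE 0.20). Extracellular matrix genes were 11 positive and 11 negative of 29 in the authors' deposited table (11 and 12 adjusted over the list alone; percentile 89.9), with Col6a3 at 2.05 (SE 0.26) and Fn1 at 1.75 (SE 0.20). Clustered protocadherins were 8 positive and 1 negative of 57 in the authors' deposited table (7 and 1 adjusted over the list alone; percentile 100, and 88.7 among members with a mean level of at least 10), led by Pcdhb19 (2.33, SE 0.56) and Pcdhb14 (2.19, SE 0.44), at mean levels of 16.4 and 25.8 normalised counts; the abundant Pcdhgc3, named after its values were seen, was the negative member (−0.29, SE 0.06) in the authors' deposited table.

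Of the 10 highest abundant genes in that authors' deposited table, 8 were of mitochondrial RNA, among them mt-Rnr1 at 7.37 (SE 0.08), mt-Rnr2 at 6.95 (SE 0.16), mt-Tl1 at 7.87 (SE 0.85), mt-Ty at 6.02 (SE 0.37), and among mRNAs mt-Atp6 at 5.11 (SE 0.17) and mt-Nd1 at 4.61 (SE 0.10). Rprl3, a ribozyme RNA, had 8.47 (SE 0.73) and Ccr4 7.51 (SE 0.66) in the authors' deposited table. The lowest apart from Uhrf1 were Bc1 (−3.02, SE 0.18), Snora57 (−2.47, SE 0.15), Spag17 (−2.42, SE 0.22) and Runx2os1 (−2.39, SE 0.14) in the authors' deposited table, followed by Col27a1, Gal, Ndufa13, Ptms and Gng13 between −2.25 and −2.21. Processed pseudogenes had a median of 0.71 against 0.03 for protein-coding genes in the authors' deposited table. Markers of other cell types that passed in the authors' deposited table, positive and negative, were 5 and 1 of 8 smooth muscle and pericyte markers (percentile 98.8, and 85.8 by the mean; Rgs5 2.18, SE 0.35), 4 and 0 of 9 endothelial (percentile 64.9; Fabp4 1.85, SE 0.43), 3 and 1 of 7 macrophage (percentile 95.8; Laptm5 2.00, SE 0.12), 3 and 0 of 7 Schwann cell (percentile 93.5; Ncam1 0.50, SE 0.08), 2 and 1 of 9 fibroblast (percentile 36.3; Pdgfra 1.38, SE 0.31) and 1 and 1 of 4 adipocyte markers, too few for a percentile. The most abundant members often had negative values in the authors' deposited table: Notch3 (−0.34, SE 0.07), Csf1r (−0.46, SE 0.16), Gsn (−0.21, SE 0.09) and Plin4 (−0.56, SE 0.23) passed, and Egfl7 (−0.63, SE 0.39), Pparg (−0.14, SE 0.27) and Thy1 (−0.03, SE 0.17) did not, while Cspg4 (0.86, SE 0.10) was positive and Mbp (0.26, SE 0.30) did not pass. Adjusted over the list alone, the macrophage counts in the authors' deposited table became 4 and 1 and the fibroblast counts 2 and 0, and the others were equal.

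Both gene tables listed 18151 genes in common. The authors' deposited tables called 3864 and 9533 of them, and 2674 in both. Of these, 978 were positive in both and 1036 negative in both, against 519 and 494 for independent lists of those sizes, and 660 had opposite signs in the authors' deposited tables. The fold changes correlated weakly across genes (Spearman rho 0.23). Among genes called in both of the authors' deposited tables, 33 histone genes were all negative, 24 of 26 replication genes were negative in both, and 11 of 14 p53 targets were positive in both, while 4 of 6 antigen presentation genes had opposite signs. Which libraries the tables share is not given in the sources used here, so part of the overlap may come from shared libraries.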

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

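Alternatives were fixed before the data were examined except the DESeq2 fit without the library labelled Control 3, the test estimate, the mean and the floor for lists, and all settings for the arms PT and PUT, which were chosen after the data were seen. The count of repeat subfamilies, 0 in edgeR with 111 at an unadjusted p below 0.05, became 17 with DESeq2, 6 without TMM factors, 63 with DESeq2 without the library labelled Control 3 and 63 in the authors' deposited table, and was 0 with DESeq2 size factors, no filter, a mean of at least 50, or stricter thresholds. Leaving out each library gave 0 to 73, and the library labelled Control 3 alone gave the 73. Of the 73, 61 were among the 63 of the authors' deposited table. With the replicate number as a block, edgeR called 0, with 154 at an unadjusted p below 0.05, while the log2 fold changes of IAPEz-int (1.40), IAPA_MM-int (1.42), IAPLTR1_Mm (1.37) and IAPLTR1a_Mm (1.16) became 3.23, 3.23, 3.07 and 2.08 (edgeR adjusted p 0.266 to 0.29). Same-numbered libraries correlated with r of 0.29, 0.071 and 0.28 (deviations from group means), and differently numbered ones with −0.29 to 0.16. Whether the numbers pair libraries is not settled by this, and the main fit kept no block. The 63 repeat calls of the authors' deposited table were 40 at an adjusted p below 0.01 and 19 with a log2 fold change of at least 1 in size, fewer by construction. Of 23 named subfamilies, 17 passed in edgeR without the library labelled Control 3, and 5 changed sign where they did not pass, nor passed over the 6 libraries: MERVL-int (0.17 to −0.03), L1Md_T (0.06 to −0.14) and MuLV-int (0.13 to −0.05) without TMM factors, and L1Md_A (−0.02 to 0.01) and L1Md_Gf (−0.06 to 0.03) without Control 1. For genes, the 3877 calls became 322 with a log2 fold change of at least 1 in size (294 higher, 28 lower) and 567 with a test estimate of at least 1 (522 higher, 45 lower). With a mean of at least 100 TPM they became 839 (243 higher, 596 lower), so the balance of directions depended on the setting. The 13112 calls of the arms PT and PUT became 5767 with a log2 fold change of at least 1 in size (3903 positive, 1864 negative). They were 8635 at a mean level of at least 100 (3509 positive, 5126 negative) and 7942 among protein-coding genes (3784 positive, 4158 negative). After recentring by −0.09 they were 13295 (7932 positive, 5363 negative). The 2014 genes with equal signs in both tables became 123 when both log2 fold changes had to reach 1. Of 21 lists, 14 lay outside the random range for Mutant over Control, 12 with the mean, 13 with the test estimate and 12 of 18 among members of at least 1 TPM, 11 of them shared. Notch genes (mean, test estimate), protocadherins (mean, floor) and germline genes (floor) then lay inside, imprinted genes lay outside above the floor (percentile 99.3), and the macrophage list had too few members above it. For the arms PT and PUT, 6 of 20 lists became 5 with the mean and 4 of 18 above a level of 10. With the mean, p53 targets (96.9) and smooth muscle markers (85.8) lay inside and DNA methylation genes (0.66) outside; above the floor, germline genes (93.5) and protocadherins (88.7) lay inside. Gene counts per library as scaling for repeats, and all fits of genes and lists that need values per library, were not run. Depth limits single calls among subfamilies with few counts, and it is unknown for genes.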

Other observations

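All tests in this part were chosen after the results were seen. Among genes outside the lists, Cyp26b1, which degrades retinoic acid, had the smallest adjusted p of the first table, rising from 15.9 TPM to 3.14 times that level (test estimate 1.63, SE 0.09, adjusted p = 6.82e-72 in the authors' deposited table). Mxd4, an antagonist of Myc, rose from 11.4 to 37.3 TPM (1.68, SE 0.10) in the same authors' deposited table and had 1.12 (SE 0.12) in that of the arms PT and PUT, where Cyp26b1 had 0.16 (SE 0.10, adjusted p = 0.171). Mdm2, higher in Mutant, had −0.25 (SE 0.07) for the arms PT and PUT in the authors' deposited table. The 13 mitochondrial mRNAs all had lower TPM in Mutant, with a median log2 fold change of −0.33 in the authors' deposited table, and 3 of them passed. Lrch1 fell from 50.2 to 10.1 TPM in the authors' deposited table, while its test estimate was −0.46 (SE 0.13). Uhrf1 itself had a wider error than most genes of its level, at percentile 99.2 of the standard errors of 1712 genes between 50 and 100 TPM in the authors' deposited table.

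The library labelled Control 3 carried summed IAP counts of 160418 CPM, against 6984 and 8629 CPM in Control 1 and Control 2 and 106643 to 210099 CPM in Mutant. An exchange with a Mutant library is argued against, because the lowest Mutant library lay 12.4 times above the higher of Control 1 and Control 2, and so is a minor admixture of Mutant RNA, since 75.4% of the highest Mutant library would be needed. A wrong label, or an exchange with a sample outside the 6, stays open. The library labelled Control 3 was placed on a scale from Control 1 and 2 (0) to the mean of all Mutant libraries (1). Its median position was 1.06 over 15 called IAP subfamilies and 0.72 (95% bootstrap interval 0.52 to 0.92) over 54 others. Each Mutant library was instead scaled to the mean of the other Mutant libraries, which widens their ranges. On that wider scale, the Mutant libraries' own medians spanned 0.61 to 1.65 and 0.61 to 1.37. These subfamilies were called higher without the library labelled Control 3, which sets Control 1 and 2 below Mutant. Single subfamilies lay on both sides of the Mutant libraries. The position was 0.53 for MMVL30-int (Mutant 0.64 to 1.34 on the wider scale) and 2.00 for MMETn-int (Mutant 0.57 to 1.41 on the wider scale). A true difference of the library labelled Control 3, such as IAP activity without loss of Uhrf1, may also account for its IAP counts and was not tested, as its Uhrf1 level was not analysed here. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05, and with 0 edgeR calls in the real split all 10 reach it by construction. The highest other, with 9 edgeR calls (57 with DESeq2 against 17), set Control 1, Control 2 and Mutant 1 against the rest. That may reflect a structure of the samples beyond the group labels, which was not tested.

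The breadth of the comparison of the arms PT and PUT, 47.2% of genes, was weighed next. A trend with GC content and transcript length as its whole cause is argued against for abundant protein-coding genes. Among 9514 with a mean level of at least 100, the 95% interval excluded the median fold change for 72.6% before and 67.8% after removal. These shares are unadjusted and of abundant genes, so they cannot be set beside the 47.2% of all genes. Library preparation or alignment that differed between the arms may contribute, since processed pseudogenes lay 0.67 (log2) and mitochondrial mRNAs 2.94 above protein-coding genes by their medians. The difference in Uhrf1 between the arms stays open beside it as an untested biological explanation.

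Xist, the RNA of the inactive X chromosome, had a log2 fold change of 9.95 (SE 1.19, mean level 88.1) where Uhrf1 was lower, and Tsix 7.22 (SE 1.28), in the authors' deposited table of the arms PT and PUT. Arms of opposite sex are argued against, because the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median of 0.39 (from −0.18 to 1.01). A small share of female cells in that arm, a preparation that differed between arms, or Xist activity in male cells with less Uhrf1 stay open as hypotheses and were not tested. These 4 genes had log2 fold changes between −0.05 and 0.05 for Mutant over Control in the authors' deposited table, which does not list Xist.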
